A study of Mus musculus with 6 samples.

How the data were processed

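The data are whole-tumour RNA libraries of 6 mouse samples, 3 treated and 3 control, grouped by the library names in the labels. Per the labels' protocols, polyadenylated RNA was selected with oligo(dT) beads and fragmented, second strands carrying uracil were removed so that the library marks strand, and paired reads of 150 bp were sequenced. The submitters' processing notes name fastp, StringTie and edgeR, with no versions or roles. The aligner, the genome build, the annotation and whether counting used strand are not given in the sources used here, so an antisense or overlapping partner cannot be excluded as a source of reads for a gene.

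The authors deposited a count and an FPKM per gene and library in 1 table of 28368 genes, each with its identifier, symbol and coordinates. The count columns, deposited by the authors as raw counts per the file headers, hold whole numbers with a different total in each library. The FPKM columns, deposited by the authors per the file headers, were used only in a check: over 11724 genes, the ratio of FPKM to count matched a constant per gene and library to within 1% for 99.8 to 99.9% of genes. One FPKM column carries an extra suffix in its header, and the counts of that library were used as named. Coordinates are given as in the table; 99.7% of the gene identifiers occur in GENCODE M21 (GRCm38) and 90.2% of genes have the same start and end there. For example, Irf7 (ENSMUSG00000025498) lies on chromosome 7 from 141262706 to 141266481, Isg15 (ENSMUSG00000035692) on chromosome 4 from 156199455 to 156200796, Ifnb1 (ENSMUSG00000048806) on chromosome 4 from 88522025 to 88522774 and Pecam1 (ENSMUSG00000020717) on chromosome 11 from 106654217 to 106750628, all as spans of whole genes. For 58 rows with a symbol held by another row, the plain symbol was kept for the row with the highest mean count.

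Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and, as an alternative, DESeq2 1.42.0. Genes were kept by filterByExpr with the groups (minimum count 10, minimum total count 15), which left 18049 genes and removed 10319, and libraries were scaled by TMM, with factors from 0.974 to 1.014. Each gene was tested with glmQLFit and glmQLFTest on the group term alone, all 6 libraries in the fit, two-sided, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The common biological coefficient of variation was 0.252. The SE of a log2 fold change is its size divided by the square root of the F statistic. Levels are in CPM, scaled by TMM, with the SD over 3 libraries. The median log2 fold change of all tested genes was -0.003. With 57017043 to 66634551 counts per library, precision for abundant genes is set mainly by the spread between libraries. For genes with few counts, among them Ifnb1, Ifna4, Ifnz, Il27 and H2-Ob, it is also limited by those counts.

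Before the data were examined, 36 gene lists of 867 different symbols, the panel of 13 pathway genes, the tests, the alternatives and the rule for naming genes were fixed. The rule names the panel, the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 1 and no overlap between groups (without predicted genes and antigen receptor segments), and up to 4 members of each list, the 3 with the smallest p and the most abundant. Genes named outside it are marked where they appear. Lists cover the STING pathway, interferon ligands, interferon-stimulated genes, interferon-gamma response, NF-kB and inflammation, chemokines, both classes of antigen presentation, checkpoints, immune cell types, stroma and vessels, epithelial, melanocyte, muscle, adipocyte, skin and red blood cells, p53, apoptosis, pyroptosis, cell cycle, unfolded protein, heat shock, hypoxia and immediate early responses, oxidative phosphorylation, mitochondrially encoded and ribosomal protein genes. Many list members are expressed by more than 1 cell type, and some genes are in more than 1 list. Each list was tested with limma's camera on log2 CPM (prior count 2, preset correlation 0.01, Benjamini-Hochberg over the lists), again with an estimated correlation, and with fry, which asks whether a list's genes move one way and compares them with no other genes. With an estimated correlation no fixed list passed the threshold, the interferon-stimulated and endothelial lists included. By fry the interferon-stimulated and endothelial lists passed (both fry adjusted p = 0.00449). So did the mitochondrially encoded (0.0384), STING and p53 lists (both 0.0464), and no other fixed list. A further 7 lists were written after the gene table had been seen and are used in the closing section only.

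On simulated counts with the real means, dispersions and library sizes and 200 changed genes, the edgeR fit recovered 9 of 50 genes changed 1.5-fold, 19 of 50 at 2-fold, 31 of 50 at 4-fold and 46 of 50 at 8-fold, with 17535 genes tested. Over 10 such simulations 112 of 1308 calls were false, 8.6% against the nominal 5%. In the simulation used for the recovery, the false share was 11% for edgeR (13 of 118 calls), 26.9% for DESeq2 (50 of 186) and 8.8% for limma-voom (10 of 114). It was also 8.8% for limma-voom with sample quality weights. A list of 40 genes shifted 1.5-fold had a camera adjusted p of 7.03e-28, and 0 of 100 unshifted random lists passed. The simulated genes were drawn independently, so this does not show how often a list of correlated genes would pass at the preset correlation. Rises and falls were also simulated in equal number, so the false shares need not hold for the real data, where rises led. Alternatives tried were DESeq2, limma-voom with and without sample quality weights, a robust fit, RLE, upper-quartile and no scaling factors, no filter and a stricter filter (1 CPM in 3 libraries), removal of the 20 most abundant genes, a fold threshold, each library left out, and the replicate number as a block. All 6 libraries and all count columns were used.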

Results

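Polyadenylated RNA from mouse tumours was sequenced in 2 groups of 3 libraries. The treated group came from mice that had received a therapy named MS-DF-MS for 12 h, and the control group from mice left untreated. The series title speaks of implanted depots that release an agonist of STING, the adaptor of cytosolic DNA sensing, followed by an inducer of apoptosis. The labels name neither drug nor tumour type. No group received an empty depot, so effects of the drugs cannot be told apart from those of an implant. The question stated for the series is how the pathway from STING to interferon-beta becomes active inside the tumour. Treated libraries 1, 2 and 3 held 64505780, 66097284 and 66634551 counts, and control libraries 1, 2 and 3 held 64172654, 64111478 and 57017043. Between 22071 and 22831 genes had at least 1 count in a library. Spearman correlations between libraries ran from 0.979 to 0.987, and a chi-square statistic per gene of 17.2 to 84.7 left no pair within sampling noise. The first principal component of log2 CPM set treated 3 apart, at 72.9 against -37.9 to 13.3 for the other 5 libraries. Transcripts of the pigment cell lineage were abundant in both groups, with Tyrp1 at 8510 ± 458 CPM in treated and 7970 ± 42.6 CPM in control tumours (SD, n = 3). The labels say that tumours came from mice in cohorts and leave open whether each library is a separate animal, so p-values measure the spread between these samples, which may be partly technical.

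Treated against control tumours, all genes. Interferon-stimulated genes led the rises. Usp18, which removes ISG15 from proteins and restrains interferon receptor signalling, rose 18.4-fold. Ifit1, a sensor of foreign RNA ends, rose 16.5-fold, and Mx2, a dynamin-like antiviral GTPase, rose 12.9-fold. Irf7, a transcription factor of interferon genes, rose from 7.83 ± 0.748 to 97.2 ± 33.7 CPM (SD, n = 3). Falls were fewer and smaller apart from Fosb, a subunit of the AP-1 transcription factor, at 73.0 ± 39.8 CPM in control and 6.50 ± 4.48 CPM in treated tumours. Of 18049 genes tested with edgeR's quasi-likelihood F test, 246 rose and 45 fell at a Benjamini-Hochberg adjusted p under 0.05, and 2891 had an unadjusted p under 0.05. Of the called genes, 148 rose and 5 fell by at least 2-fold, with a median log2 fold change of 1.18 among the genes that rose and -0.52 among those that fell. All 291 called genes had the 3 treated libraries on one side of the 3 controls, against 23.3% of all tested genes and the 10% that chance gives. A call from 3 against 3 libraries nearly requires such a gap, so its presence in all called genes is no separate evidence. The 8 largest rises under the naming rule began with Ifit1bl1 (log2 fold change 5.06 ± 0.39 SE, edgeR adjusted p = 0.000668), Usp18 (4.20 ± 0.24, 0.000305), Ifit1 (4.05 ± 0.27, 0.000348) and Slfn4 (4.04 ± 0.52, 0.00944). The other 4 were Ifit3b (3.83 ± 0.25, 0.000348), Mx2 (3.69 ± 0.23, edgeR adjusted p = 0.000305), Oas3 (3.64 ± 0.49, 0.0127) and Irf7 (3.63 ± 0.25, 0.00036). Ifit, Oas and Slfn genes have close paralogs that can share reads, so the split within each family is uncertain. The 8 largest falls began with Fosb (-3.49 ± 0.59, edgeR adjusted p = 0.0313), Hlf, a circadian output factor (-1.43 ± 0.20, 0.0147), B3galt5 (-1.22 ± 0.14, 0.00475) and Egr1, an immediate early factor (-1.14 ± 0.15, 0.00998). The other 4 were Sik1 (-0.97 ± 0.15, 0.0215), Lrp8 (-0.92 ± 0.15, 0.0268), Kctd12 (-0.84 ± 0.13, 0.0224) and Cirbp, a cold-inducible RNA-binding protein (-0.70 ± 0.08, 0.00387). With each library left out in turn, 89 of the 246 rises kept their call every time and 2 of the 45 falls did, B3galt5 and Cirbp. The number of rises was 120 without treated 2, 127, 113 and 94 without controls 1, 3 and 2, and 308 without treated 3, and the number of falls was 6, 9, 7, 3 and 39. Of the genes named, Slfn4 lost its call without each control (edgeR adjusted p up to 0.0837), Oas3 without treated 2 and each control (up to 0.0949), and Fosb without each library but control 1 (up to 0.134). Hlf lost its call without treated 2 and controls 1 and 2 (edgeR adjusted p up to 0.101), and Egr1 (up to 0.0709) and Sik1 (up to 0.12) without controls 2 and 3. Lrp8 lost its call without treated 2 and each control (edgeR adjusted p up to 0.147), and Kctd12 without treated 1 and 2 and controls 1 and 2 (up to 0.123).

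Type I interferon-stimulated genes. Almost the whole list moved up in every treated tumour. Ddx58, the RNA sensor RIG-I, rose 8.05-fold (223.6 ± 7.03 against 27.8 ± 3.47 CPM, SD, n = 3; edgeR adjusted p = 3.85e-05). Dhx58, a relative of RIG-I, rose 9.57-fold, Rtp4 rose 7.72-fold (both edgeR adjusted p = 0.000305) and Lgals3bp rose 2.03-fold (0.000692). Of 49 members tested, 45 rose and none fell, and 47 rose when adjusted over the list alone. The members that missed the threshold over all genes, named after their values were seen, were Epsti1, Zbp1, Slfn1 and Ifi27l2a, with log2 fold changes from 0.95 (Epsti1) to 1.87 (Slfn1). Zbp1 passed without treated 3 (edgeR adjusted p = 0.0118). The list's median log2 fold change was 2.44, and its median against the control mean was 2.77, 2.75 and 2.15 in treated 1, 2 and 3. By camera the list stood above the other genes (adjusted p = 2.41e-53), with adjusted p = 0.349 with an estimated correlation, which was 0.508 between its genes. By fry, which compares the list with no other genes, it passed (fry adjusted p = 0.00449). Of the 45 calls, 30 held without each library in turn, among them those of Ddx58, Dhx58, Rtp4, Lgals3bp, Isg15, Ifit1 and Mx2.

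**Figure D1:**
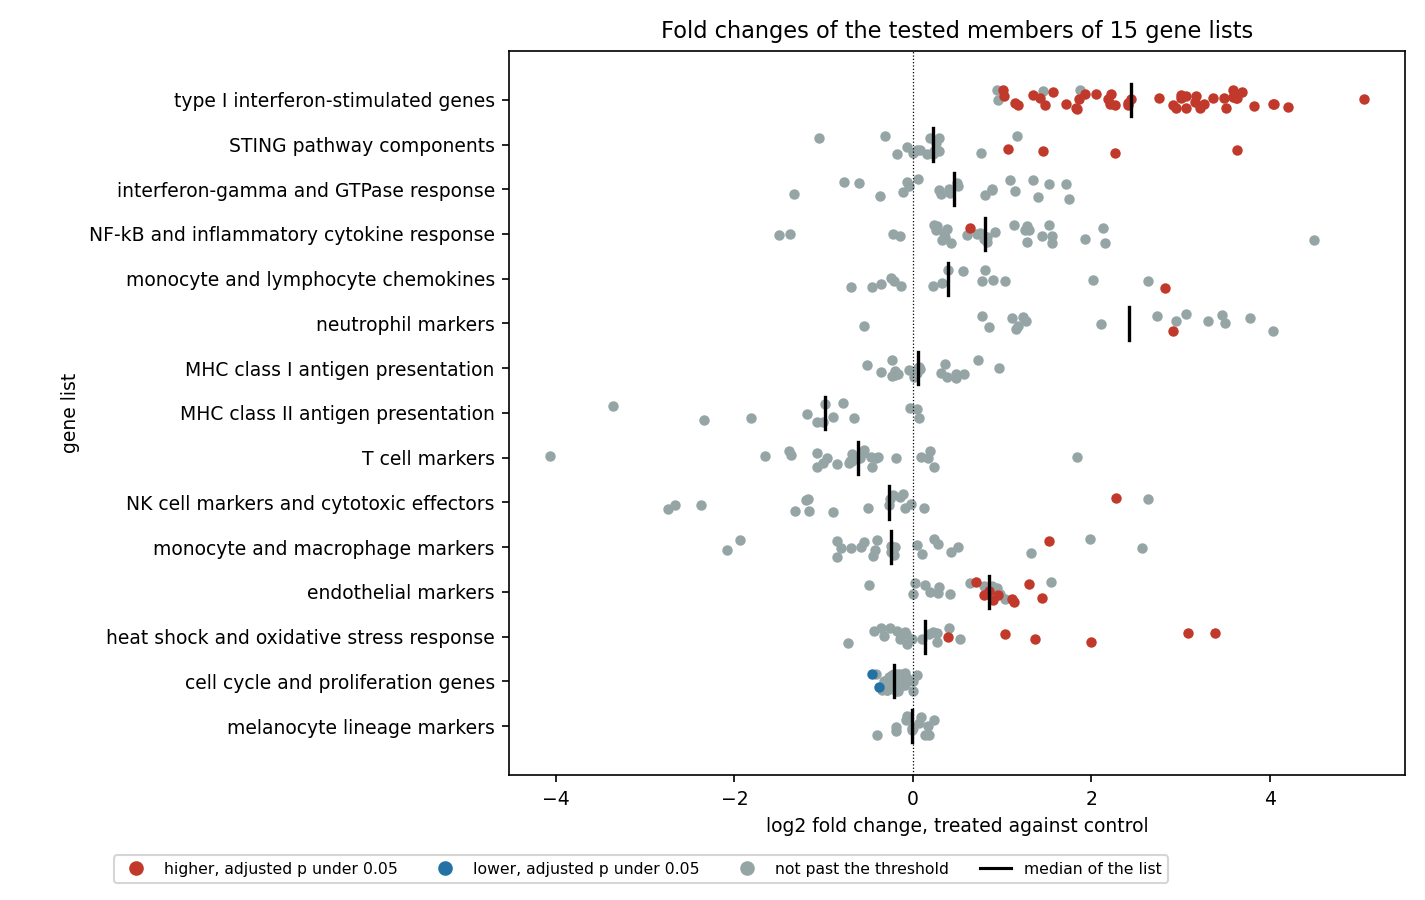
Log2 fold change of treated against control tumours for each tested member of 15 gene lists, with the list median as a black bar and members past an edgeR adjusted p of 0.05 in red (higher) or blue (lower). The interferon-stimulated list lies to the right of 0 with a median of 2.44, and the endothelial list has a median of 0.85. Retnla of the monocyte and macrophage list, with 0 counts in the treated libraries, is not drawn and counts in its list's median.

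STING pathway and interferon-beta. The mRNAs of the sensor, adaptor, kinase and factor upstream of interferon did not pass the threshold, while Irf7 and Isg15, which respond to interferon, rose. RNA levels at 12 h do not measure whether the upstream proteins were active. Isg15, a ubiquitin-like modifier, rose from 19.0 ± 3.47 to 196.2 ± 44.3 CPM (log2 fold change 3.37 ± 0.20 SE, n = 3, edgeR adjusted p = 0.000305). Of the 13 genes of the panel fixed for the pathway, Irf7 and Isg15 rose and the other 11 did not pass the threshold. Sting1 had a log2 fold change of 0.30 ± 0.10 (edgeR adjusted p = 0.226), Cgas, the DNA sensor that feeds it, 0.23 ± 0.19 (0.624), Tbk1, its kinase, 0.16 ± 0.08 (0.374), and Irf3, the factor that kinase phosphorylates, 0.19 ± 0.09 (0.339). The groups did not overlap for Sting1, Tbk1 and Irf3, as for 23.3% of all tested genes, and overlapped for Cgas. Small rises of these genes are not excluded, since the simulation recovered 9 of 50 genes changed 1.5-fold. Ifnb1, the gene of interferon-beta, had 20, 95 and 7 counts in treated 1, 2 and 3 and 15, 5 and 0 in the controls, a log2 fold change of 2.57 ± 1.25 (edgeR adjusted p = 0.363). Of the other ligands of type I and III interferons, Ifna4 had 5 counts in treated 1 and 0 elsewhere and Ifnz had 2 to 10 counts in each library, both below the filter. The ligand list thus had 1 tested member, camera adjusted p = 0.364, with 0 calls by edgeR, DESeq2 or limma-voom, 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone. Of the 20 STING pathway components, 4 rose and none fell: Irf7, Ifi35 (1.46 ± 0.14, edgeR adjusted p = 0.00216), the ubiquitin ligase Trim56 (1.06 ± 0.12, 0.00488) and the DNA sensor Ifi204 (2.27 ± 0.33, 0.0185), the last named after its value was seen. All are also known to be induced by interferon. Adjusted over the list alone, 8 rose and 1 fell. The median was 0.23, camera adjusted p = 0.000319, adjusted p = 0.451 with an estimated correlation, and fry adjusted p = 0.0464. The call of Ifi204 was lost without treated 2 and without each control (edgeR adjusted p up to 0.126).

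**Figure D2:**
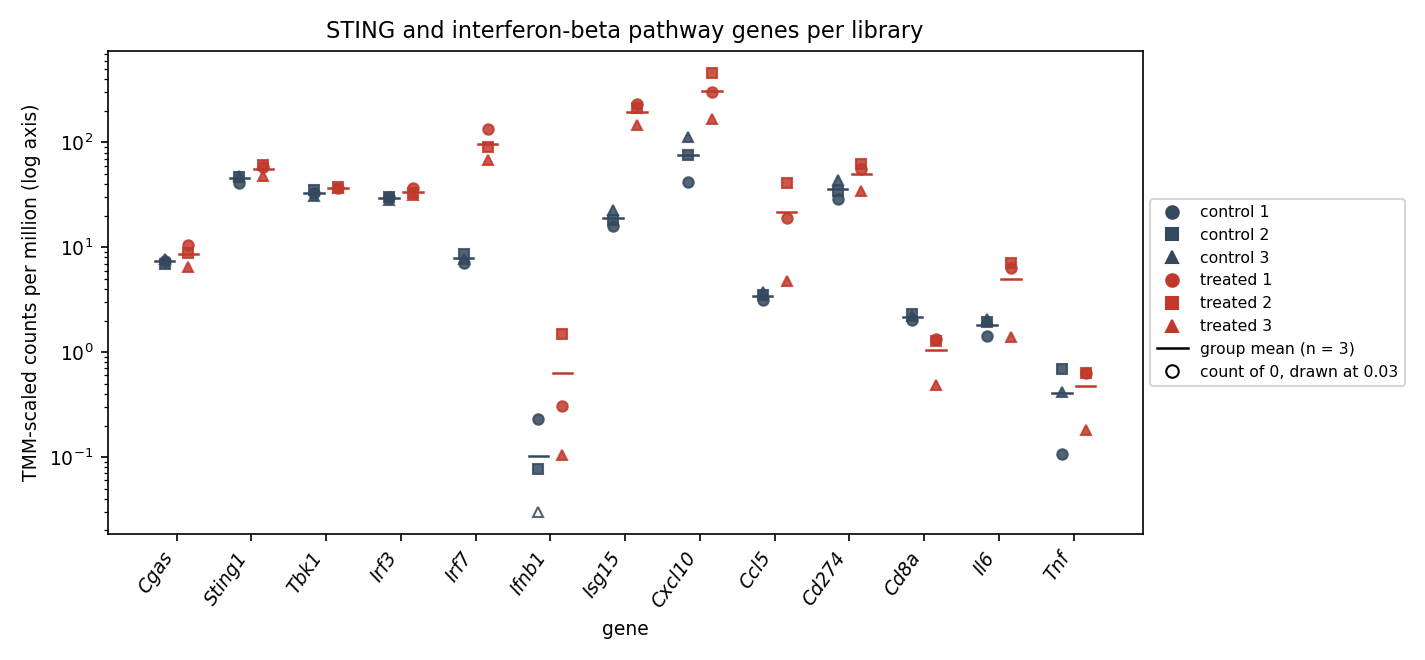
TMM-scaled CPM on a log axis for the 13 panel genes, with 1 marker per library and a bar at each group mean (n = 3). Irf7 and Isg15 in the treated libraries lie above all controls, at means of 97.2 and 196.2 CPM against 7.83 and 19.0.

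Chemokines and inflammatory cytokines. Cxcl11, a ligand of the chemokine receptor CXCR3, rose 7.07-fold (5.69 ± 2.84 against 0.806 ± 0.350 CPM, SD, n = 3; edgeR adjusted p = 0.032). Cxcl10, another CXCR3 ligand, stood at 309.7 ± 147.7 against 76.5 ± 34.8 CPM (log2 fold change 2.02 ± 0.43, edgeR adjusted p = 0.0732) and Ccl5 at 21.6 ± 18.3 against 3.47 ± 0.302 CPM (2.64 ± 0.64, 0.105). Relb, a subunit of NF-kB, rose 1.56-fold (edgeR adjusted p = 0.0464), while Il27 (4.50 ± 1.10, 0.105), Nfkb1 (0.26 ± 0.07, 0.131), Il6 (1.45 ± 0.54, 0.243) and Tnf (0.23 ± 0.75, 0.922) missed the threshold. Il27 rests on few counts, with 0 in 2 of the 3 controls. The chemokine list had 1 of 17 members up and 3 when adjusted over the list alone (median 0.39, camera adjusted p = 0.253). The NF-kB and inflammatory list had 1 of 34 up and 11 when adjusted over the list alone (median 0.80, camera adjusted p = 7.65e-05, adjusted p = 0.707 with an estimated correlation). Its median against the control mean was 1.28 in treated 1, 0.94 in treated 2 and -0.18 in treated 3. Without treated 3, the panel count was 5: Cxcl10 (edgeR adjusted p = 0.026, range over its alternatives 0.00722 to 0.289), Ccl5 (0.00277) and Il6 (0.00932) passed the threshold beside Irf7 and Isg15, and the chemokine list was higher (camera adjusted p = 0.00129). The call of Cxcl11 was kept only in that setting among the leave-outs (up to 0.187 otherwise) and that of Relb in none of them (0.0508 to 0.238).

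Interferon-gamma response and antigen presentation. No member of these lists passed the edgeR threshold over all genes. At an unadjusted p under 0.05 there were 7 in the interferon-gamma, 5 in the MHC class I and 2 in the MHC class II list, DESeq2 called 2, 1 and 0, limma-voom none, and limma-voom with sample quality weights 3, 0 and 0. Irgm2, an immunity-related GTPase, had a log2 fold change of 1.52 ± 0.32 (n = 3, edgeR adjusted p = 0.0665), Gbp3 1.34 ± 0.34 (0.112), and Cd274, which encodes the checkpoint ligand PD-L1, 0.49 ± 0.23 (0.342). Among MHC class I genes H2-Q6 had 0.96 ± 0.29 (0.174) and B2m, the light chain, 0.01 ± 0.20 (0.987). H2-Q genes are near-identical copies and their read split is uncertain. Among MHC class II genes H2-Ob had -2.34 ± 0.61 (0.121), H2-DMa -1.19 ± 0.53 (0.323) and Cd74, the invariant chain, -0.78 ± 0.65 (0.625). H2-Ob rests on few counts, at 0.0966 CPM in treated tumours. The interferon-gamma list of 24 tested genes had 0 calls and 2 when adjusted over the list alone (median 0.46, camera adjusted p = 0.0397, adjusted p = 0.857 with an estimated correlation), and its camera call was lost without treated 1 (0.38), treated 2 (0.34) or control 1 (0.397). Its medians in treated 1, 2 and 3 against the control mean were 0.86, 0.98 and -0.37. Without treated 3, Irgm2 (edgeR adjusted p = 0.0256), Gbp3 (0.0441) and H2-Q6 (0.00622) passed the threshold. The 22 MHC class I genes had 0 calls either way, including adjusted over the list alone. Their median was 0.05 with camera pointing down (adjusted p = 0.992), and without treated 3 camera pointed up (adjusted p = 0.00357). The 13 MHC class II genes had 0 calls, also adjusted over the list alone, a median of -0.98 and a lower position by camera (adjusted p = 0.00108, adjusted p = 0.707 with an estimated correlation), with medians of 0.02, -1.06 and -2.06 in treated 1, 2 and 3 against the control mean.

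Lymphoid and myeloid markers and checkpoint genes. The ligand Tnfsf10 (TRAIL), which triggers death receptors, rose 4.84-fold (7.39 ± 2.86 against 1.53 ± 0.590 CPM, SD, n = 3; edgeR adjusted p = 0.0286). Checkpoint genes that rose were Lgals9, encoding galectin-9 (log2 fold change 1.48 ± 0.09, edgeR adjusted p = 0.000305), Cd200 (1.56 ± 0.22, 0.0159), Cd47, the signal against phagocytosis (0.73 ± 0.11, 0.018), and, named after its value was seen, the ectonucleotidase Nt5e (1.78 ± 0.28, 0.0215). Hdc, which makes histamine and is in the neutrophil list, rose 7.52-fold (edgeR adjusted p = 0.0497), and the neutrophil protein gene S100a8 stood at 5.73 ± 6.13 against 0.349 ± 0.230 CPM (0.0794). Plac8 rose 2.88-fold (0.0198), and the dendritic list's calls were Bst2, itself interferon-inducible (2.02-fold, 0.0397), Tnfsf9 (0.62 ± 0.11, 0.0423) and Relb. Cd8a had a log2 fold change of -1.07 ± 0.39 (0.24), and Tcf7 -0.59 ± 0.20 (0.198). The T cell list had 0 of 27 calls, also adjusted over the list alone, a median of -0.62 and a lower position by camera (adjusted p = 0.000725, adjusted p = 0.707 with an estimated correlation), with medians of -0.06, -0.57 and -1.31 in treated 1, 2 and 3. The NK and cytotoxic list had 1 of 19 up and 2 adjusted over the list alone, with a median of -0.27 (camera adjusted p = 0.00467, adjusted p = 0.707 with an estimated correlation). Its camera call ended without treated 3 (0.319) and pointed up under a stricter filter (0.816). The neutrophil list had 1 of 18 up and 4 adjusted over the list alone, a median of 2.42 (camera adjusted p = 0.000998, adjusted p = 0.707 with an estimated correlation) and medians of 3.33, 1.80 and -0.21 in treated 1, 2 and 3, and its call ended without treated 1 (0.0821). The checkpoint list had 4 of 18 up and 4 adjusted over the list alone (median 0.08, camera adjusted p = 0.253). The dendritic list had 3 of 22 up and, adjusted over the list alone, 5 up and 2 down (median 0.28, camera adjusted p = 0.211), and the monocyte and macrophage list 1 of 26 up and, adjusted over the list alone, 2 up and 1 down (median -0.25, 0.522). B cell markers had 0 of 11 calls (camera adjusted p = 0.262) and mast cell, eosinophil and basophil markers 0 of 4 (0.979), with 0 adjusted over the list alone in both. At an unadjusted p under 0.05 the T cell, B cell and mast cell lists had 5, 1 and 0, DESeq2 and limma-voom with sample quality weights each called 1, 1 and 0, and limma-voom without weights none. Lgals9 held its call without each library in turn. Without treated 2 and each control, calls were lost for Tnfsf10 (edgeR adjusted p up to 0.163), Cd200 (0.0862), Cd47 (0.109), Plac8 (0.126), Bst2 (0.195, also without treated 3) and Hdc (0.239, also without treated 1). S100a8 passed without treated 3 (0.0227). The call of Nt5e was lost without treated 1 and 2 and controls 2 and 3 (0.106), and that of Tnfsf9 in each leave-out (0.226). The checkpoint count was 1 without treated 2 or controls 2 or 3 and 2 without control 1. By camera the dendritic (0.0319) and checkpoint (0.0136) lists passed as higher without treated 3. The monocyte (0.00908) and B cell lists (0.0486) passed as lower without treated 1.

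Vessels and matrix. Of 25 endothelial markers 9 rose, among them genes of cell junctions and adhesion, and 16 did not pass the threshold. Pecam1, the adhesion molecule CD31, rose 2.46-fold (40.9 ± 2.92 against 16.6 ± 0.426 CPM, SD, n = 3; edgeR adjusted p = 0.000348), Robo4 rose 2.73-fold (0.0017) and Cdh5, the cadherin of endothelial junctions, rose 2.16-fold (0.00295). Eng, the most abundant marker, had a log2 fold change of 0.20 ± 0.05 (0.131), and Vwf, named after its value was seen, had -0.49 ± 0.20 (0.284). None fell, and 14 rose when adjusted over the list alone. The list's median was 0.85 overall and 0.68, 0.87 and 0.72 in treated 1, 2 and 3 against the control mean (camera adjusted p = 5.63e-11, adjusted p = 0.145 with an estimated correlation, fry adjusted p = 0.00449). Kcnj8, a potassium channel of pericytes, rose 2.24-fold (0.0355), the 1 call of 11 in the pericyte and smooth muscle list (2 adjusted over the list alone, median 0.26, camera adjusted p = 0.0134, adjusted p = 0.707 with an estimated correlation). Col6a1 (0.63 ± 0.08, edgeR adjusted p = 0.00799) and Col6a3 (0.53 ± 0.09, 0.0265), chains of collagen VI, were the 2 calls of 26 in the fibroblast and matrix list (3 adjusted over the list alone, median 0.26, camera adjusted p = 0.00467, adjusted p = 0.743 with an estimated correlation). Pecam1, Robo4 and Cdh5 kept their calls without each library in turn, and the number of endothelial markers up was 3 without treated 2, and 4, 3 and 5 without controls 1, 2 and 3. Without control 3 the pericyte and fibroblast camera calls ended (0.148 and 0.402), as they did without treated 3 (0.0918, pericyte) and treated 1 (0.0509, fibroblast). The calls of Kcnj8 (edgeR adjusted p up to 0.194) and Col6a3 (up to 0.141) were lost without treated 2 and 3 and controls 2 and 3, that of Kcnj8 also without control 1, and that of Col6a1 without control 2 (0.0699).

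Stress responses and cell death. Several inducible chaperones of the heat shock response rose. Hspa1b and Hspa1a, which encode the inducible HSP70 and are near-identical copies whose reads may be split, rose 10.5-fold and 8.46-fold (edgeR adjusted p = 0.00571 and 0.005), and their cochaperone Dnajb1 rose 2.59-fold (118.9 ± 28.7 against 45.9 ± 3.38 CPM, SD, n = 3; 0.00637). Hspb1 (log2 fold change 2.00 ± 0.28, edgeR adjusted p = 0.0152), Hsph1 (1.03 ± 0.17, 0.0285) and Hspa8 (0.39 ± 0.07, 0.0313), named after their values were seen, rose as well, and Hsp90aa1 had 0.22 ± 0.11 (edgeR adjusted p = 0.361). Trp53inp1 (0.79 ± 0.14, 0.0423) and Btg2 (1.06 ± 0.20, 0.049), both targets of p53, rose, and Cdkn1a, the inhibitor p21, had 0.67 ± 0.13 (0.0529). Bcl2l11, which encodes the death-promoting protein BIM, rose 1.53-fold (0.049), and Asns, asparagine synthetase, rose 1.26-fold (0.0287). Ddit4, P4ha2 and P4ha1 of the hypoxia list rose 1.74-fold, 1.57-fold and 1.42-fold (edgeR adjusted p = 0.00402, 0.0185 and 0.0221). The heat shock and oxidative stress list had 6 of 24 up and, adjusted over the list alone, 10 up and 4 down (median 0.14, camera adjusted p = 0.0737). The p53 list had 2 of 28 up and 9 adjusted over the list alone (median 0.23, camera adjusted p = 0.000319, adjusted p = 0.451 with an estimated correlation). The hypoxia and glycolysis list had 4 of 33 up, with Mxi1, named after its value was seen, as the other member, and 9 adjusted over the list alone (median 0.10, camera adjusted p = 0.0017, adjusted p = 0.707 with an estimated correlation). Apoptosis machinery had 2 of 30 up, Tnfsf10 and Bcl2l11, and 5 adjusted over the list alone (median 0.03, camera adjusted p = 0.147). The unfolded protein list had 1 of 28 up and, adjusted over the list alone, 1 up and 2 down (median -0.10, 0.164), and pyroptosis and necroptosis genes had 0 of 18 by either count, adjusted over the list alone included (median 0.15, 0.53; 4 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma-voom and 1 with sample quality weights). Without treated 3 the heat shock list (camera adjusted p = 0.00357) and the pyroptosis list (0.0146) passed, both as higher. The heat shock count was 3, 1 and 3 without controls 1, 2 and 3, and the hypoxia count was 9 without treated 1, 2 without treated 2 and 1 without each control. Hspa1a and Ddit4 kept their calls without each library in turn. Hspa1b (0.0541) and Dnajb1 (0.0602) lost theirs without control 2. Hspb1 lost its call without treated 2 and each control (edgeR adjusted p up to 0.0942), Hsph1 without each library but treated 3 (up to 0.159) and Hspa8 without each but treated 2 (up to 0.192). Trp53inp1 and Bcl2l11 lost theirs in all 6 leave-outs (up to 0.192). Btg2 lost its call without each library but treated 3 (edgeR adjusted p up to 0.223), Asns without each but treated 1 (up to 0.206), P4ha2 without each control (up to 0.116) and P4ha1 without these and treated 2 (up to 0.137). Cdkn1a passed without treated 3 (0.048).

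**Figure D3:**
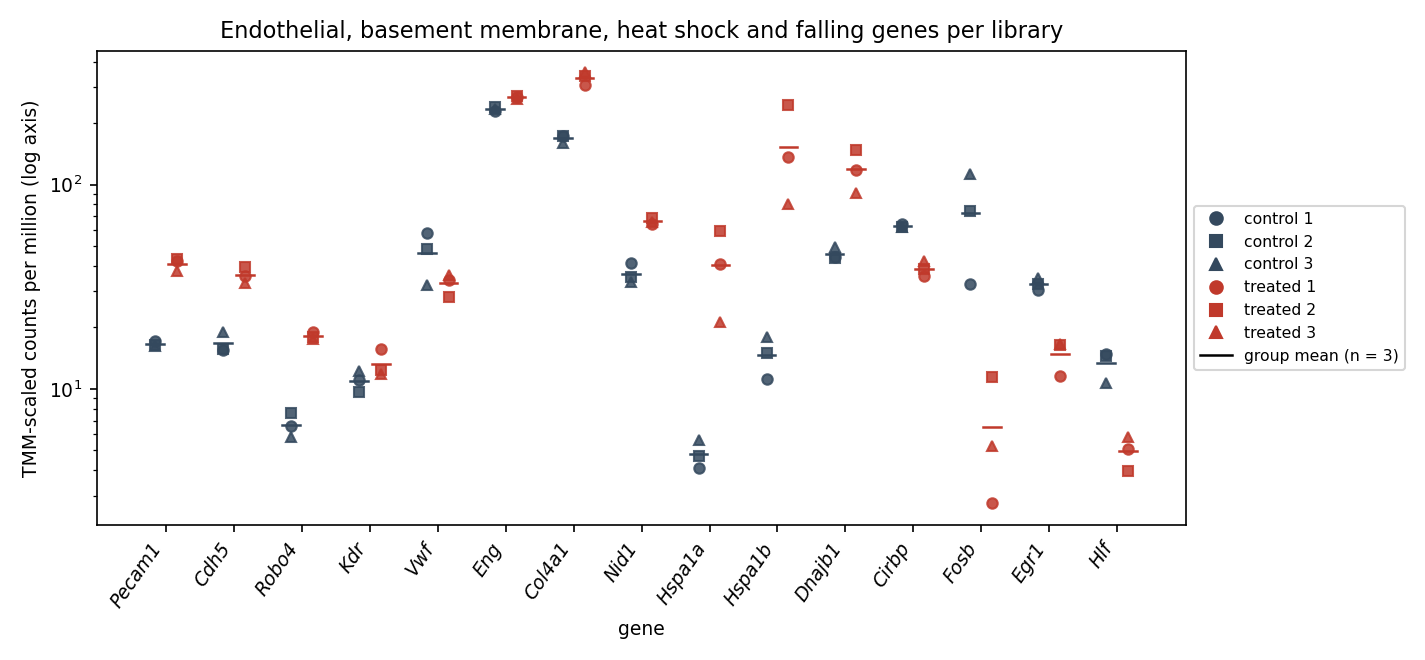
TMM-scaled CPM on a log axis for endothelial, basement membrane, heat shock and falling genes, with 1 marker per library and a bar at each group mean (n = 3). Pecam1 lies at 40.9 CPM in treated and 16.6 CPM in control tumours, and Fosb at 6.50 and 73.0 CPM.

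Proliferation, tumour lineage and other tissue. Tk1, thymidine kinase (log2 fold change -0.38 ± 0.06 SE, n = 3, edgeR adjusted p = 0.0303), and Ccne1, cyclin E1 (-0.45 ± 0.08, 0.0427), fell, and Top2a had -0.18 ± 0.09 (0.353). The cell cycle list had 2 of 38 down, also when adjusted over the list alone, with 36 members negative, a median of -0.21 and medians of -0.22, -0.19 and -0.18 in the 3 treated libraries (camera adjusted p = 4e-09, adjusted p = 0.707 with an estimated correlation). Immediate early genes had 2 of 27 down, Fosb and Egr1, and 1 up, Btg2, with the same numbers adjusted over the list alone (median -0.11, camera adjusted p = 0.682). Melanocyte lineage genes had 0 of 14 calls (median near 0 at -0.01, camera adjusted p = 0.88), with Pmel at 0.18 ± 0.06 (edgeR adjusted p = 0.209), and only 5 of 20 epithelial markers passed the filter, with 0 calls (0.774). Skeletal muscle (0 of 26 calls, camera adjusted p = 0.114), skin keratinocyte (0 of 2, 0.467), adipocyte (0 of 13, 0.795) and red blood cell genes (0 of 9, 0.0647) had no call over all genes. Adjusted over the list alone the melanocyte, epithelial, muscle and skin lists had 0, the adipocyte list 2 and the red blood cell list 4. At an unadjusted p under 0.05 the melanocyte, epithelial, muscle, skin, adipocyte and red blood cell lists had 3, 1, 1, 0, 4 and 4 genes, while DESeq2 called 3 adipocyte genes and 1 red blood cell gene, limma-voom none, and limma-voom with sample quality weights 1 adipocyte gene. By camera, muscle passed as lower without treated 1 (1.58e-06) or control 3 (0.035). Skin passed as higher without treated 2 (0.0198), and red blood cell genes as higher without treated 2 (0.00972), treated 3 (0.0266), control 2 (0.0355) or control 3 (0.0211). The muscle median was 0.01 while camera pointed down, and the epithelial median was 0.08 with a mean of -0.01. Medians against the control mean in treated 1, 2 and 3 were 1.34, -0.91 and -2.61 for muscle and 3.08, 0.52 and 0.55 for red blood cell genes, with Hbb-bs at 577.5, 198.8 and 105.6 CPM and 38.2 to 84.1 CPM in the controls (edgeR adjusted p = 0.122, and 0.0366 without treated 3). Of the genes encoded by mitochondria, mt-Nd1 rose 1.35-fold (edgeR adjusted p = 0.00624), mt-Nd6 1.72-fold (0.0185) and mt-Nd5 1.78-fold (0.02), with 3 of 13 up and 11 adjusted over the list alone (median 0.22, camera adjusted p = 6.17e-07, adjusted p = 0.451 with an estimated correlation). Nuclear copies of these genes can share their reads. Mitochondrial genes took 3.80, 3.63 and 3.35% of counts in the treated and 3.03, 3.00 and 3.22% in the control libraries. Oxidative phosphorylation genes encoded in the nucleus had 0 of 35 calls (camera adjusted p = 0.812), and cytosolic ribosomal protein genes had 0 of 42 (median 0.08, camera adjusted p = 0.00249, adjusted p = 0.707 with an estimated correlation), both 0 adjusted over the list alone. At an unadjusted p under 0.05 they had 0 and 9, and DESeq2 and limma-voom, with or without weights, called none. The call of Tk1 was lost without each library but treated 1 (edgeR adjusted p up to 0.198), that of Ccne1 without each but control 1 (up to 0.239). Calls were lost for mt-Nd5 (up to 0.135) and mt-Nd6 (up to 0.128) without each control, mt-Nd6 also without treated 2, and for mt-Nd1 without control 2 (0.0805).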

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

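The alternatives here were chosen before the data were examined. The lists added for the closing section, and its tests of explanations apart from that of the regrouped libraries, were chosen after seeing the data. No gene called in the main comparison changed sign in any of 17 settings. That was close to fixed in advance, since no called gene had overlapping groups. The numbers of genes up and down, 246 and 45, became 754 and 367 with DESeq2 and 601 and 191 with limma-voom and sample quality weights. Their false shares in 1 simulation of independent genes were 26.9% and 8.8%, which need not hold for the real data. With a 2-fold threshold the numbers were 148 and 5. Without a filter, which tests 28368 genes, 164 rose and 10 fell. With 1 library left out they ranged from 94 to 308 and from 3 to 39. Fewer samples enter these fits. The other scalings, filters and fits gave 219 to 289 up and 44 to 64 down. The panel count of 2 became 5 with DESeq2, and ranged from 2 to 5 over the leave-outs, the highest without treated 3. With an estimated correlation the list p was 0.451 for STING components and 0.349 for interferon-stimulated genes. With the preset correlation (0.000319 and 2.41e-53) the leave-outs ranged from 6.66e-05 to 0.00211 and from 8.92e-54 to 4.74e-41. No leave-out was run with an estimated correlation. The MHC class I list turned up without treated 3 (adjusted p = 0.00357, range over its alternatives 0.00357 to 0.998, over the leave-outs 0.00357 to 0.979) and the NK list turned up under the stricter filter (0.816, range 7.43e-05 to 0.816), where fewer members are tested. The cause was otherwise not tested. Replicate numbers are shared between groups, but deviations of same-numbered libraries correlated at 0.086, -0.164 and -0.107, so nothing shows that they pair samples, and not every library correlated best with its own number. With the replicate number as a block, 123 genes rose and 14 fell, 121 and 11 of them shared with the main comparison.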

Other observations

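All lists in this part, and all tests but that of the regrouped libraries, were chosen after the gene table had been seen. The criterion for Rbm3 is recorded as set before its result, but for a pattern already seen and with an added list. Of 15 basement membrane genes 6 rose and 9 did not pass the threshold. Col4a1 and Col4a2, the chains of collagen IV, rose 1.99-fold and 2.02-fold (edgeR quasi-likelihood adjusted p = 0.000559 and 0.000692, Benjamini-Hochberg), and Nid1 and Nid2 rose 1.81-fold and 1.82-fold (0.00299 and 0.00249), each call kept without every library in turn. The list had camera adjusted p = 9.57e-08, and adjusted p = 0.129 with an estimated correlation. Edn1, endothelin-1, rose 8.05-fold (4.77 ± 0.755 against 0.594 ± 0.382 CPM, SD, n = 3; edgeR adjusted p = 0.0349), Bmp6 rose 6.64-fold (0.0223), and the Notch ligand Dll4 rose 2.13-fold (0.0368), among 5 of 20 genes of vascular growth and Notch signalling (camera adjusted p = 6.27e-07, adjusted p = 0.0329 with an estimated correlation). Edn1 lost its call without each library but control 1 (up to 0.167), Bmp6 without each but treated 1 (up to 0.133) and Dll4 without each but treated 3 (up to 0.207). All 5 calls of this list were lost without treated 2 and without control 2, and all but 1 without controls 1 and 3. The 7 added lists were written with the gene table in view and were adjusted among themselves only. Their camera p-values therefore restate in part the rises and falls already seen, the 0.0329 of this list included.

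ADP-ribosyltransferases split by member. Parp14, Parp12 and Parp10 rose 4.55-fold, 3.42-fold and 2.96-fold (edgeR quasi-likelihood adjusted p = 0.00813, 0.00216 and 0.00216, Benjamini-Hochberg), while Parp1, the DNA damage enzyme, had a log2 fold change of -0.23 ± 0.06 (0.13). Of 13 members 6 rose (camera adjusted p = 1.47e-05, adjusted p = 0.177 with an estimated correlation). The count was 3 without treated 2 and 2 without control 2, where Parp12 and Parp10 kept their calls and Parp14 (0.0634), Parp9 (0.0809), Parp11 (0.118) and Parp3 (0.14) lost theirs. Parp14 is also in the fixed interferon-stimulated list.

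The 6 libraries can be split into 3 and 3 in 10 ways, and 1 of these, the real one, called as many genes as observed: 291, against a highest of 3 among the others. With 10 splits no share under 0.05 can be reached.

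Endothelial markers up. A smaller share of tumour cells alone would raise every other cell type alike, but the endothelial median exceeded the T cell median by at least 0.75 (log2) in each treated library. The MHC class II median also lay below the endothelial median in each. These values do not bear on a smaller tumour cell share beside a change in T cells themselves. Melanocyte lineage medians against the control mean were -0.04, 0 and 0.08 in treated 1, 2 and 3. A larger share of endothelial cells would move its markers by a common fold, yet over 24 markers the fold changes differed beyond their errors (p = 4.3e-19 by a chi-square test of heterogeneity with small SEs raised to the median, approximate since each SE rests on 3 against 3 libraries), with Vwf at -0.49 and Pecam1 at 1.30. Other cells also express some markers, Eng among them, which would add to such differences, so a larger share beside such expression stays open. An endothelial response to interferon had also been listed, and its test was dropped once its values were seen, although they met the criterion set against it. That criterion turned on endothelial medians of 0.72 in treated 3 and 0.68 in treated 1, too close in single libraries to count either way. A change of expression inside endothelial cells was not tested.

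Heat shock genes up with Cirbp, Srsf5, Fosb and Egr1 down. Srsf5 had a log2 fold change of -0.67 ± 0.11 (edgeR quasi-likelihood adjusted p = 0.0276, Benjamini-Hochberg), 1 of 3 falls among 12 SR splicing factors (camera adjusted p = 0.0807, and 0.0167 without control 1), and lost its call without treated 2 and each control (up to 0.15), as all 3 did without treated 2 and controls 2 and 3, and all but 1 without treated 1 and control 1. Slower handling of the controls would raise immediate early genes in them, and it cannot be told apart from the therapy: Fosb and Egr1 fell, while 14 of 27 such genes were lower in treated tumours and 13 higher, a count that had been set as the criterion against it and was set aside after it was seen, since members that go both ways decide nothing. A warmer tumour or a heat shock factor response could account for part: Rbm3, the other cold-inducible gene, had -0.18 ± 0.06 with all libraries separated, short of the threshold (0.189), and 7 of 24 heat shock factor targets rose (camera adjusted p = 1.02e-06, adjusted p = 0.276 with an estimated correlation), a list that holds the genes that drew attention and had 4 calls without treated 2 and 3, 1 and 3 without controls 1, 2 and 3. The list of 2 cold-inducible genes likewise holds Cirbp and restates its fall (camera adjusted p = 0.00533, adjusted p = 0.129 with an estimated correlation). Time of day at collection, which the labels do not give, cannot be told apart from the therapy: 6 of 19 clock genes passed when adjusted within the list, with Arntl up (0.47 ± 0.12) and Dbp, Tef, Hlf, Cry1 and Cry2 down, but Nr1d1 was at -0.05 ± 0.19 (camera adjusted p = 0.0457, adjusted p = 0.456 with an estimated correlation, and 0.495, 0.0504, 0.052 and 0.0728 without treated 1 and controls 1, 2 and 3).

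Inflammatory and neutrophil genes above the controls in treated 1 and 2 and not in treated 3. For treated 2, muscle in the piece is argued against by a muscle median of -0.91. The red blood cell median of treated 2 differed from treated 3 by -0.03, while the neutrophil medians were 1.80 and -0.21. That difference met the criterion set against blood, but abundant globin genes were higher in treated 2 than in treated 3. Hbb-bs stood at 198.8 against 105.6 CPM and Hba-a2 at 84.2 against 42.3 CPM, so more blood in treated 2 stays open. For treated 1, muscle, skin and blood medians all lay above the highest control (3 of 3 lists), so other tissue in that piece may contribute there. Against the control mean, treated 3 also had the lowest medians of the treated libraries in lists of other leukocytes. In treated 1, 2 and 3 they were 0.37, -0.51 and -1.31 for monocytes and macrophages and -0.06, -0.67 and -1.39 for NK cells. The endothelial (0.68, 0.87 and 0.72) and pericyte lists (0.23, 0.05 and 0.59) were not lowest there. The lack of a rise in treated 3 thus does not by itself show a weaker response. A different strength of response between animals was not tested.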
